A study of Mus musculus with 2 samples.

How the data were processed

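H3K9ac was mapped by ChIP-seq in midbrain tissue of mice on postnatal day 0 in 2 samples, biological replicates 1 and 2 per the labels, each from its own pool of animals of both sexes. Replicate 1 came from 15 mice per the labels. The replicates are separate biosamples per the labels, so the spread between them covers pools of animals and library preparation together.

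The authors deposited 4 peak lists in narrowPeak layout on the mouse build mm10, per the file notes. The lists of replicates 1 and 2 were called on each replicate's alignments, and the pooled list on the alignments of both, each with 2 control files, per the file notes. The replicated list was drawn from the other 3 lists, per the file notes, and the rule of replication, the peak caller and the aligner are not given in the sources used here. The deposited fold enrichment is a linear ratio of signal over control at the summit, the authors' own value for each peak. It was used to describe, rank, filter and compare peaks within a list. Between lists it was correlated over shared peaks, and the steps of its values were compared. The deposited −log10 values used here are −log10 of each peak's q-value, as the authors' caller gave them within each list. The authors' lists start at a −log10 q of 0.297 in replicate 1, 0.317 in replicate 2 and 0.373 in the pooled list, so they hold peaks well below common thresholds. Peaks with q at or below 0.01 made up 75.7% of the list of replicate 1, 59.8% of that of replicate 2 and 98.7% of the replicated list. The number of reads per sample is unknown, so the precision that depth gives to a single peak could not be computed. A low q in a list reflects depth and enrichment together, and a gene without a peak was not detected at this depth, which does not show that the mark was absent.

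Peaks on the 21 main chromosomes were used. Left out were 9, 7, 10 and 8 peaks on other scaffolds in the lists of replicate 1, replicate 2, pooled and replicated peaks, and the −log10 p column of each list, because q carries the same order with adjustment. The text notes hold no measurements and were read for provenance. No peak ended beyond its chromosome in the GRCm38 reference, whose chromosome names and lengths were checked against the lists. Gene starts came from the GENCODE annotation of that build, as 54361 unique starts of protein-coding transcripts of 21853 protein-coding genes. Coordinates are 1-based on GRCm38, and a gene's start and end span all its annotated transcripts.

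Peaks were called overlapping with at least 1 bp in common. Overlap between replicates, and between peaks and promoters (1 kb either side of a start), was compared with 100 random placements of the peaks on the same chromosomes by a one-sided permutation test. A gene was called marked when a replicated peak overlapped 1 kb either side of any of its coding starts, and its breadth was the number of bases covered by replicated peaks within 5 kb either side of its widest-covered start. A gene with more annotated starts thus had more chances to be marked or widely covered, and no test matched genes on that number. Distal peaks lay over 5 kb from any annotated start of any gene type. Promoter and distal peaks were compared by the difference of medians with 100000 resamples. Each gene list was compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 29 lists, and breadth was compared with 10000 random sets of marked genes for the 17 lists with at least 5 marked genes. Lists of other cell types and tissues were included to show what the dissection could hold. One erythroid gene of the fixed lists was not in the annotation.

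Named genes followed a rule fixed, with the lists, tests and the first set of alternatives, before the data were examined. In each list of the nervous system the 3 marked members with the widest coverage and up to 3 unmarked members in list order are named. For the whole genome these are the 10 genes with the highest fold, the 10 with the widest coverage, the 5 strongest distal peaks and the 3 strongest peaks of each replicate alone. Distances are to the nearest protein-coding start, except where a noncoding gene is named with its own distance or the gene that holds the peak is named. Neither shows that a peak acts on a gene.

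Alternatives were the pooled list, the stricter 50% of the replicated list by q, windows of 500 and 2500 bp, each replicate's own list at q of 0.01 or less (all its peaks for promoter against distal peaks), a 50% reciprocal overlap, equally long lists, breadth within 2500 bp and a distal distance of 20 kb. Alternatives added later were 1 random shift of all peaks around each chromosome, leaving out genes with a neighbouring coding start within 2 kb, a background without olfactory and vomeronasal receptors, and random genes matched on promoter CpG ratio. That ratio of observed to expected CpG was taken over 500 bp either side of each start, with the highest value per gene, in 10 strata.

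The replicate overlap, gene list, breadth and median tests were run on simulated data or lists with fixed seeds, and coverage was checked base by base. The other tests, among them promoter placement and those with CpG-matched genes, were not run on simulated data. For lists drawn from 21853 genes with an unadjusted p under 0.05, Fisher's exact test called 97% of simulated lists of 20 genes with 20% marked and 97.5% of those with 95% marked, and 2% of lists with the share of all genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used. Percentages carry exact (Clopper-Pearson) 95% intervals.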

Results

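Acetylation of lysine 9 of histone H3 (H3K9ac), a mark found at promoters of active genes, was mapped by chromatin immunoprecipitation and sequencing in the midbrain of mouse pups on postnatal day 0. The midbrain holds the dopaminergic neurons of the ventral tegmentum, GABAergic and glutamatergic neurons of the tectum and tegmentum, and their glia. There was 1 group with 2 biological replicates, each made from a separate pool of pups of both sexes. Replicate 1 was a pool of 15 mice, and the number in the pool of replicate 2 was not given in the sources used here. The measurements were 4 lists of peaks, 1 for each replicate, 1 from the reads of both replicates pooled, and 1 of peaks called replicated. On the main chromosomes replicate 1 had 62997 peaks covering 31.7 Mb, and replicate 2 had 59021 peaks covering 30.0 Mb. The pooled list held 83841 peaks over 43.8 Mb, and the replicated list held 29538 peaks over 30.3 Mb, or 1.11% of those chromosomes. Read depth was unknown, so no value carries a depth-based interval, and percentages carry exact (Clopper-Pearson) 95% intervals that cover counting error only. With a single tissue and age, the comparisons are between replicates, between places in the genome and between groups of genes.

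The first comparison asked whether both pools of midbrain gave peaks at the same places. Of the peaks of replicate 1, 49.0% (48.6 to 49.4%) overlapped a peak of replicate 2, and 53.2% (52.8 to 53.6%) of the peaks of replicate 2 overlapped a peak of replicate 1. Random placement of the other replicate's peaks gave 2.47% and 2.62% on average, and no more than 2.64% and 2.80%. The one-sided permutation p was 0.0099 for both, the smallest that 100 placements can give. Shared peaks were the strong and wide ones. The median fold enrichment in replicate 1 was 5.55 for shared peaks and 3.38 for peaks found in that replicate alone, with median widths of 560 and 202 bp. In replicate 2 these were 4.89 and 3.26, with 519 and 213 bp. Every peak in the strongest 10% of either list by q was shared (100%), against 17.0% of the weakest 10% of replicate 1 and 21.6% of that of replicate 2.

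**Figure D1:**
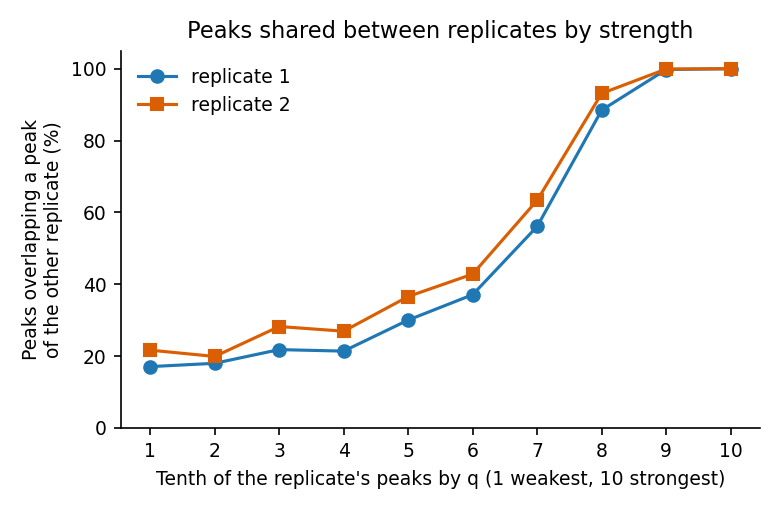
Percentage of each replicate's peaks (vertical axis) that overlapped a peak of the other replicate, in 10 equal parts of the list ordered by q from weakest to strongest (horizontal axis), with circles for replicate 1 and squares for replicate 2. The share was 17.0% and 21.6% in the weakest 10% and 100% in the strongest 10% of both.

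Across the 30844 peaks of replicate 1 that overlapped a peak of replicate 2, the authors' fold enrichment correlated between the lists, with a Pearson correlation of 0.79 on the log2 scale and a Spearman correlation of 0.76. These are correlations across peaks, which are not independent replicates, so no p is given. The strongest peaks seen in replicate 1 alone lay 46112 bp from the start of Ubash3b (chromosome 9, 41207650 to 41208019, fold 8.33), at the promoter of Cnpy2 (chromosome 10, 128321720 to 128322139, fold 8.12) and 73611 bp from Vmn2r112 (chromosome 17, 22674275 to 22674758, fold 7.98). In replicate 2 alone they lay at the promoter of Cep131 (chromosome 11, 120086902 to 120087211), 346 bp from the noncoding gene Dancr (chromosome 5, 74092535 to 74092863) and in an exon of Atn1 (chromosome 6, 124745218 to 124745468), each with a fold of 6.85. None of these 6 came near the strongest peaks of their lists, which reached 38.9 in replicate 1 and 29.7 in replicate 2.

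The replicated list kept the strong part of the pooled list. It held 35.2% of the pooled peaks, and every one of its 29538 peaks had the same position, fold and q in the pooled list. All pooled peaks in the strongest 10% by fold enrichment were kept (100%), and 99.9% of the next 10%. In the stronger 50% of the pooled list 66.2% were kept, against 4.27% in the weaker 50%, an odds ratio of 43.9 (95% interval 41.7 to 46.2). The p of Fisher's exact test for that difference was too small for the software to represent. Of the replicated peaks, 26015 (88.1%) overlapped a peak of both replicates' own lists, and 3523 did not.

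H3K9ac lay mostly at gene starts. Of the replicated peaks, 16700 of 29538 overlapped the window of 1 kb either side of a protein-coding start, which is 56.5% (56.0 to 57.1%). Random placement on the same chromosomes gave 3.81% on average and 4.04% at most (one-sided permutation p = 0.0099, the smallest that 100 placements can give). By the position of the summit, 54.2% lay within 1 kb of a coding start, 4.03% in exons elsewhere, 23.4% in introns and 18.4% outside coding genes. Randomly placed peaks fell there in 2.59%, 2.54%, 35.4% and 59.4% of cases. The promoter share depended on how strong the peaks were, and was 26.4% in the pooled list and 85.2% in the stronger 50% of the replicated list by q.

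**Figure D2:**
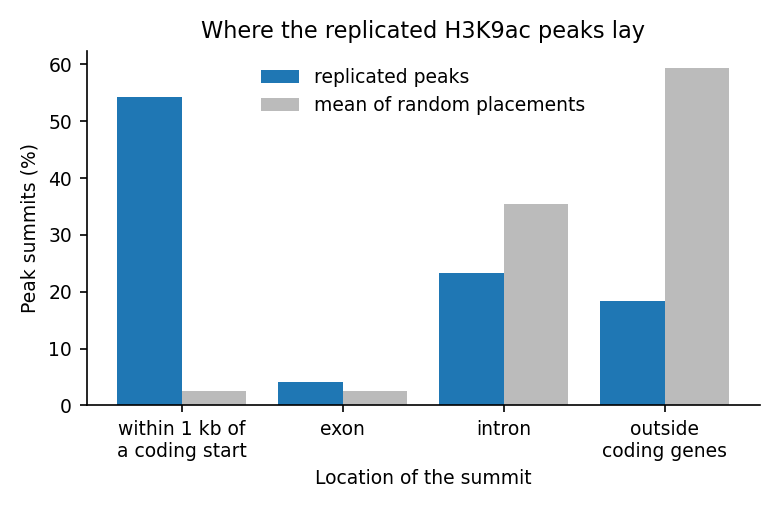
Percentage of replicated peak summits (vertical axis) within 1 kb of a protein-coding start, in exons elsewhere, in introns and outside coding genes (horizontal axis), in blue, beside the mean of 20 random placements, in grey. Summits within 1 kb of a start made up 54.2% against 2.59% at random, and summits outside coding genes 18.4% against 59.4%.

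Promoter peaks were stronger and wider than peaks far from any annotated start, which could still lie within genes. The 16700 replicated peaks at promoters had a median fold enrichment of 9.20 (quartiles 5.41 and 13.9) and a median width of 1175 bp. The 6006 peaks over 5 kb from any annotated start had a median fold of 3.80 (3.30 and 4.44) and a median width of 460 bp. Both differences, 5.40 in fold and 715 bp in width, had a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give. Peaks are not independent replicates. In the replicates' own lists the medians were 6.94 and 3.47 for replicate 1 and 6.20 and 3.26 for replicate 2, so the difference was smaller there, 3.47 and 2.93 (permutation p = 1e-05 in each).

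The strongest distal peaks had folds above the upper quartile of promoter peaks. The first lay on chromosome 9 at 32031554 to 32033490 (GRCm38), outside coding genes and 83552 bp from the nearest coding start, that of Arhgap32, with a fold of 20.99. The second lay in an intron of Ldb3, which encodes a protein of the muscle Z-disc (chromosome 14, 34548293 to 34549990, fold 18.9). The others lay on chromosome 17 at 22080836 to 22081613 85041 bp from the start of Zfp947 (17.6), on chromosome 1 at 165280408 to 165284023, 13629 bp from Gpr161, a receptor of the primary cilium (17.4), and on chromosome 17 at 88255801 to 88257598 184440 bp from the start of Foxn2 (17.2).

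Of 21853 protein-coding genes, 13567 had a replicated peak at a start, 62.1% (61.4 to 62.7%). The highest fold enrichment belonged to Actb, the gene of beta-actin (chromosome 5, 142903115 to 142906754), with 36.2 in the replicated list, 32.3 in replicate 1 and 29.7 in replicate 2. It was followed by the splicing factor gene Srsf6 (34.4), the nuclear import receptor gene Tnpo1 (33.8), the gamma-actin gene Actg1 (33.6) and the RNA-binding protein gene Rbm39 (33.4). Marcksl1 (33.0), Zc3h4 (33.0), the neuronal polarity kinase gene Brsk1 (32.6), Cirbp (32.2) and Fam117b (30.99) completed the 10 highest. The genes with the widest coverage were others. Kdm6b, which encodes a demethylase of histone H3 lysine 27 (chromosome 11, 69398508 to 69413675), was covered over 9946 bases within 5 kb of its start, followed by Tnrc18 with 9822. The homeobox gene Meis2 had 9710 bases and Myt1l, a neuronal zinc finger factor, had 9542. The LIM homeobox genes Lhx9 and Lhx5 had 9540 and 9404. Pou3f3 had 9308, the histone methyltransferase gene Setd1b 9265, the Wnt pathway factor gene Tcf7l2 9204 and Bcl11a 9081. The peak of 11029 bp at Setd1b had its summit 55 bp from the start of the noncoding gene 4932422M17Rik and 3317 bp from that of Setd1b. Its breadth may thus not be that of Setd1b alone. A marked gene had a median of 1777 covered bases (quartiles 1205 and 2470).

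The replicates marked nearly the same genes. With peaks of q at or below 0.01, replicate 1 marked 13714 genes and replicate 2 marked 13353, of which 13100 were marked in both. Only 341 genes marked in replicate 1 had no peak of any q in replicate 2, and 184 the other way round. A start of another protein-coding gene lay within 2 kb for 3169 genes, so a peak there cannot be assigned to 1 of them.

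Pan-neuronal, glutamate and GABA receptor and housekeeping genes were marked almost without exception. Of 29 gene lists fixed before the data were examined, 8 were marked more often than the other protein-coding genes, of which about 62.1% were marked. All 20 pan-neuronal genes were marked (Fisher's exact test with Benjamini-Hochberg adjustment, p = 0.000384), among them Elavl4, an RNA-binding protein of neurons (5572 covered bases), Tubb3, neuronal tubulin (5485), and the synaptic adhesion gene Nrxn1 (5131). Of 26 glutamate and GABA receptor genes 25 were marked (adjusted p = 0.000466, Fisher's exact test), led by Grin2d (6743 bases), Gabbr1 (6700) and Grik2 (5132). The 1 unmarked member was Gabra6, known from cerebellar granule cells. Of 15 neural progenitor genes 14 were marked (adjusted p = 0.0266, Fisher's exact test), including Msi1 (6350 bases), the stem cell factor Sox2 (6345) and the Notch target Hes5 (5195), and Neurog1 was not. Of 13 tectal and glutamatergic midbrain factors 12 were marked (adjusted p = 0.0395, Fisher's exact test), among them Tfap2b (8094 bases), Ebf3 (7457) and the vesicular glutamate transporter gene Slc17a6 (6003), while Isl1 was not.

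The other 4 lists marked more often were marked in full. They were 25 ribosomal protein genes (adjusted p = 4.64e-05, Fisher's exact test), 18 housekeeping genes (0.000769), 18 enzymes of histone acetylation and deacetylation (0.000769) and 12 immediate early genes such as Fos, Egr1 and Npas4 (0.0104). When each list was compared with random genes matched on promoter CpG ratio, an alternative chosen after seeing the data, 2 of the 8 lists were still marked more often, the pan-neuronal genes (adjusted permutation p = 0.00902) and the receptor genes (0.0087). With another window, a stricter list or a background without receptor families the adjusted p of the tectal list was 0.0681 to 0.189, and with a stricter list or a 500 bp window that of the neural progenitors was 0.0909 and 0.0975 (Fisher's exact test).

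**Figure D3:**
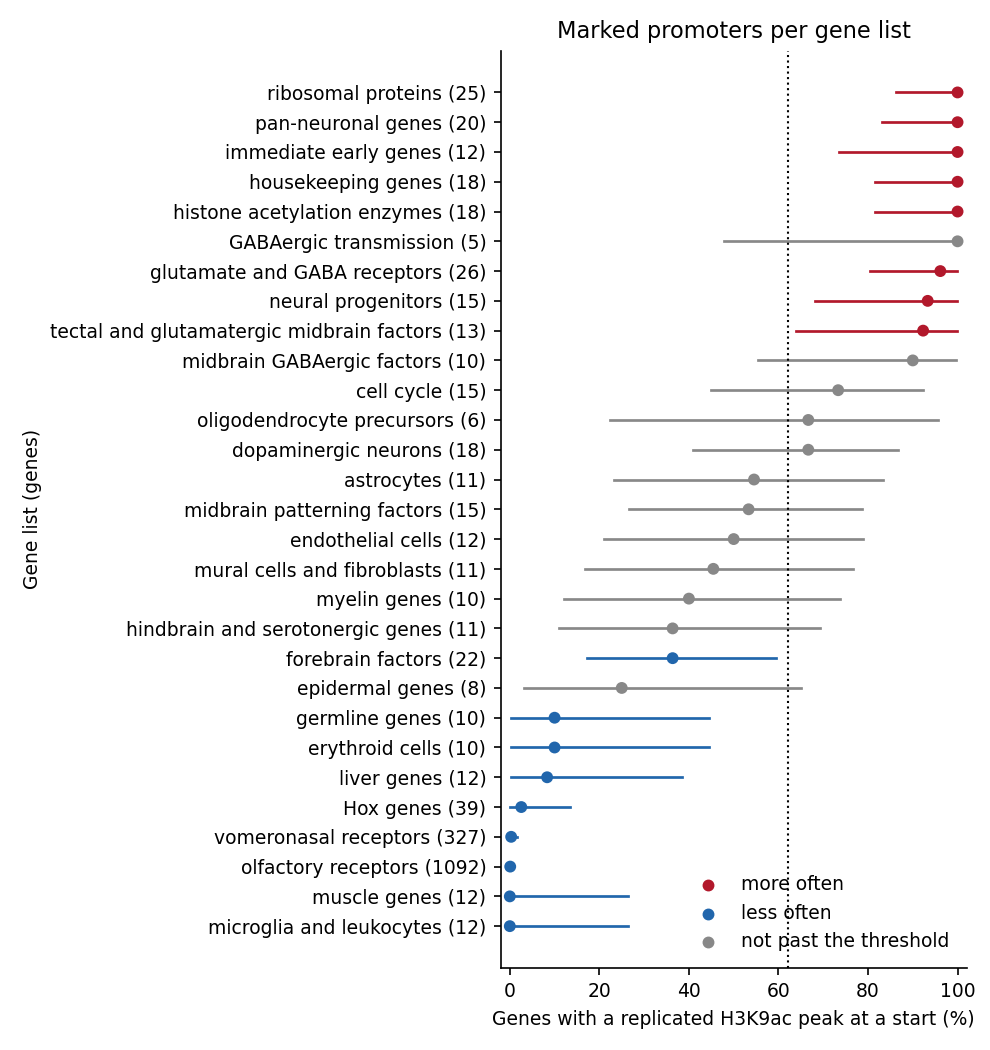
Percentage of the genes of each list with a replicated H3K9ac peak at a start (horizontal axis, points, with exact 95% intervals as lines) for 29 lists, with the number of genes in brackets. The dotted line is the 62.1% of all protein-coding genes, and colours give lists marked more often (8), less often (9) and not past the threshold (12).

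Genes of other body regions, of microglia and leukocytes and of several other tissues were mostly unmarked, with 9 lists marked less often than other genes. Of 39 Hox genes, which pattern the hindbrain and spinal cord, 1 was marked (adjusted p = 2.24e-14, Fisher's exact test). This was Hoxa7 (chromosome 6, 52214491 to 52221854), with 376 covered bases and folds of 4.40 and 4.89 in replicates 1 and 2, and Hoxa1, Hoxa2 and Hoxa3 were among the unmarked ones. Replicate 1's own list marked 3 of the 39, and the pooled list 15.4%, still less often than other genes. The 39 genes lie in clusters on chromosomes 2, 6, 11 and 15 and are not independent. Each p for Hox genes here and below thus overstates the evidence. Of 22 forebrain factors 8 were marked (adjusted p = 0.0283, Fisher's exact test). The widest of these were Lhx2 (7793 bases), Bcl11b (5269) and Emx2 (2816). Foxg1, Tbr1 and Fezf2, known from the telencephalon and cortex, were unmarked. The forebrain call was lost with replicate 1's own list (9 of 22, adjusted p = 0.0731, Fisher's exact test). It was lost too without genes with a neighbouring start (0.0838, Fisher's exact test), although no forebrain factor was left out and the share stayed 8 of 22. In the pooled list 68.2% were marked.

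None of 12 microglial and leukocyte genes was marked (exact interval up to 26.5%, adjusted Fisher p = 4.64e-05), nor any of 12 muscle genes (same interval and p). One liver gene of 12, Apoa1 (adjusted p = 0.000585), 1 erythroid gene of 10, Klf1 (0.00237), and 1 germline gene of 10, Dazl (0.00237), were marked, each by Fisher's exact test. These 3 genes are named after their values were seen, as the exceptions of their lists. Among 1092 olfactory receptor genes 1 was marked, and among 327 vomeronasal receptor genes 1 (adjusted p = 2.63e-136, Fisher's exact test). The test counts neighbouring family members as independent, so this p may overstate the evidence. Replicate 1's own list marked 2 of the 12 microglial genes (adjusted p = 0.00358, Fisher's exact test). In the pooled list the calls of the microglial (50%, adjusted p = 0.296) and erythroid lists (30%, 0.0635) were lost, and against CpG-matched genes the calls of the microglial (adjusted permutation p = 0.387), liver (0.971) and erythroid lists (1) were lost.

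The markers of midbrain dopaminergic neurons were divided. Of 18 genes 12 were marked, among them the patterning factors En1 (7279 bases) and En2 (6316), and Sox6 (3097). Another coding gene's start lies within 2 kb of a start of Sox6, so its peak may not be its own. Th, the rate-limiting enzyme of dopamine synthesis (chromosome 7, 142892752 to 142931128), Ddc, the next enzyme, and Lmx1a, a factor of dopaminergic progenitors, were unmarked. In the replicates' own lists Th had a peak in replicate 1 alone (fold 3.82), as did Lmx1a (3.47), and both had a peak in the pooled list, which marked 83.3% of the 18 genes. The share of 66.7% did not differ from other genes (adjusted p = 0.84, Fisher's exact test). The call rested on which replicate was used. In replicate 1's own list 16 of the 18 were marked (adjusted p = 0.0439, Fisher's exact test), and in replicate 2's 11 (adjusted p = 1).

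No other list passed the threshold. All 5 genes of GABAergic transmission were marked (adjusted p = 0.227, Fisher's exact test), led by Gad1 (8259 bases) and Gad2 (6334), the enzymes that make GABA, and its vesicular transporter Slc32a1 (8228). Of 10 midbrain GABAergic factors 9 were marked (adjusted p = 0.154, Fisher's exact test), led by Lhx5 (9404 bases), Gata3 (8542) and Lhx1 (8517), and Helt was not. Of 15 midbrain patterning factors 8 were marked (adjusted p = 0.665, Fisher's exact test), led by Meis2 (9710), Otx2 (7450) and En1 (7279). Pax2, Pax8 and Fgf8 were unmarked. Of 11 hindbrain and serotonergic genes 4 were marked (adjusted p = 0.169, Fisher's exact test), the widest being Mafb (1842), Egr2 (648) and Slc6a4 (610), and Ptf1a, Phox2a and Phox2b were unmarked. Against CpG-matched genes the patterning and hindbrain lists were marked less often (53.3% against 92.3% and 36.4% against 88.6%, adjusted permutation p = 0.000967 for each), whereas the pooled list marked 86.7% and 72.7% of them. The hindbrain list was also marked less often in the stricter list (9.09%, adjusted p = 0.00742) and with a 500 bp window (18.2%, 0.0092, both by Fisher's exact test).

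Glial lists were marked in part. Of 11 astrocyte genes 6 were marked (adjusted p = 0.814, Fisher's exact test). The widest were the transcription factor Nfib (7201 bases), the glutamate transporter Slc1a2 (3727) and Nfia (3230), whereas Gfap, Aqp4 and Aldh1l1 were unmarked. Another coding gene's start lies within 2 kb of a start of Nfia, so its peak may not be its own. Of 6 genes of oligodendrocyte precursors 4 were marked (adjusted p = 1, Fisher's exact test), led by Olig2 (3333), Olig1 (2349) and Pdgfra (1714), and Sox10 and Gpr17 were not. Of 10 myelin genes 4 were marked (adjusted p = 0.256, Fisher's exact test), the widest being Mbp (2111), Cnp (1564) and Cldn11 (630), and Plp1, Mog and Mag were unmarked. The rest were 11 of 15 cell cycle genes (adjusted p = 0.506), 6 of 12 endothelial genes (0.47), 5 of 11 genes of mural cells and fibroblasts (0.443) and 2 of 8 epidermal genes (0.0969), all by Fisher's exact test. In the stricter list the precursor (0%, adjusted p = 0.0137), endothelial (16.7%, 0.0137) and mural lists (0%, 0.000433) were marked less often, as were epidermal genes in the pooled list (25%, 0.0372), with a 500 bp window (12.5%, 0.0122) and without receptor families in the background (25%, 0.0372, all by Fisher's exact test). A list of 10 genes of which 20% are truly marked would be called in 78.5% of simulations at an unadjusted p under 0.05, and one of which 95% are marked in 59.5%, so small lists can miss differences.

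Regional identity was compared directly between lists. Midbrain patterning factors were marked in 8 of 15 cases and Hox genes in 1 of 39. The difference was 50.8 percentage points (two-sided Fisher's exact test, p = 4.81e-05), and 33.3 points in the stricter list (p = 0.00095, Fisher's exact test). Hox genes lie in clusters, so p of any comparison with them overstates the evidence. The difference between midbrain patterning factors and the 8 of 22 forebrain factors was 17.0 percentage points and did not pass the test (p = 0.336, Fisher's exact test). Further pairs were chosen after the data were seen, and p was adjusted over all 6 pairs. Forebrain factors were marked more often than Hox genes by 33.8 points (adjusted p = 0.00224, Fisher's exact test). Midbrain GABAergic factors exceeded forebrain factors by 53.6 points (adjusted p = 0.011), and tectal and glutamatergic factors did so by 55.9 points (adjusted p = 0.00303, both by Fisher's exact test). In the pooled list the 3 shares were 90%, 100% and, for forebrain factors, 68.2%, so both gaps were smaller there, and they were not tested. The dopaminergic list and the GABAergic factors did not differ detectably (adjusted p = 0.364, Fisher's exact test). The adjusted p of the first pair was 0.000289 and of the second 0.364.

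Several lists of midbrain neuron genes were among those with the broadest H3K9ac at marked promoters. Marked genes of GABAergic transmission were covered over a median of 6334 bases within 5 kb of the start (5 genes, quartiles 3702 and 8228), and midbrain patterning factors over 4962 bases (8 genes, 2587 and 7322). Midbrain GABAergic factors had 4487 bases (9 genes, 3060 and 8517), and tectal and glutamatergic factors had 4240 bases (12 genes, 3086 and 5893). Random sets of marked genes had medians near 1778. For each of these 4 lists, and for pan-neuronal genes (3381 bases) and receptor genes (3074), the adjusted permutation p was 0.000567, at the smallest unadjusted p of 0.0002 that 10000 random sets can give. Immediate early genes (3111 bases, 0.00291), housekeeping genes (2660, 0.0068), ribosomal protein genes (2372, 0.0266) and astrocyte genes (3012, 0.0368) were also wider by the same permutation test. Breadth counts every replicated peak within 5 kb, so peaks of neighbouring genes can add to it. The unmarked muscle gene Acta1, for example, had 1539 covered bases. No breadth test left out genes with a neighbouring start.

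Marked dopaminergic genes were narrower than random marked genes, with a median of 1087 bases over 12 genes (adjusted permutation p = 0.0262). The 5 narrowest marked members, named after their values were seen, were the transcription factor gene Foxa1 (395 bases), the dopamine transporter gene Slc6a3 (588), the vesicular monoamine transporter gene Slc18a2 (700), Gch1 (783) and Drd2 (905). Of the 12, only En1 (9.64), En2 (12.8) and Sox6 (9.60) had a fold above 9.20, the median of all replicated promoter peaks. Breadth was not compared at equal fold. The tissue was not sorted, so breadth in dopaminergic neurons themselves was not measured. Cell cycle genes were narrower too, with 991 bases over 11 genes (0.0159). Forebrain factors (2203 bases, adjusted permutation p = 0.29), neural progenitor genes (2369, 0.0884), histone acetylation enzymes (2274, 0.0903), endothelial genes (1132, 0.116) and genes of mural cells and fibroblasts (1251, 0.266) did not pass the threshold against random marked genes. The dopaminergic list shared En1, En2, Lmx1b and Foxa2 with the patterning list. Without replicate 1 the dopaminergic call was lost (973 bases, adjusted permutation p = 0.0939), and in the pooled list the patterning factors had 1706 bases (0.498) and the forebrain factors 770, narrower than random marked genes (0.00105). The wider call was lost for ribosomal protein genes against CpG-matched genes (adjusted permutation p = 0.0671) and without replicate 1 (0.232), and for astrocyte genes without replicate 1 (0.0526), without replicate 2 (0.079) and in the pooled list (0.245).

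**Figure D4:**
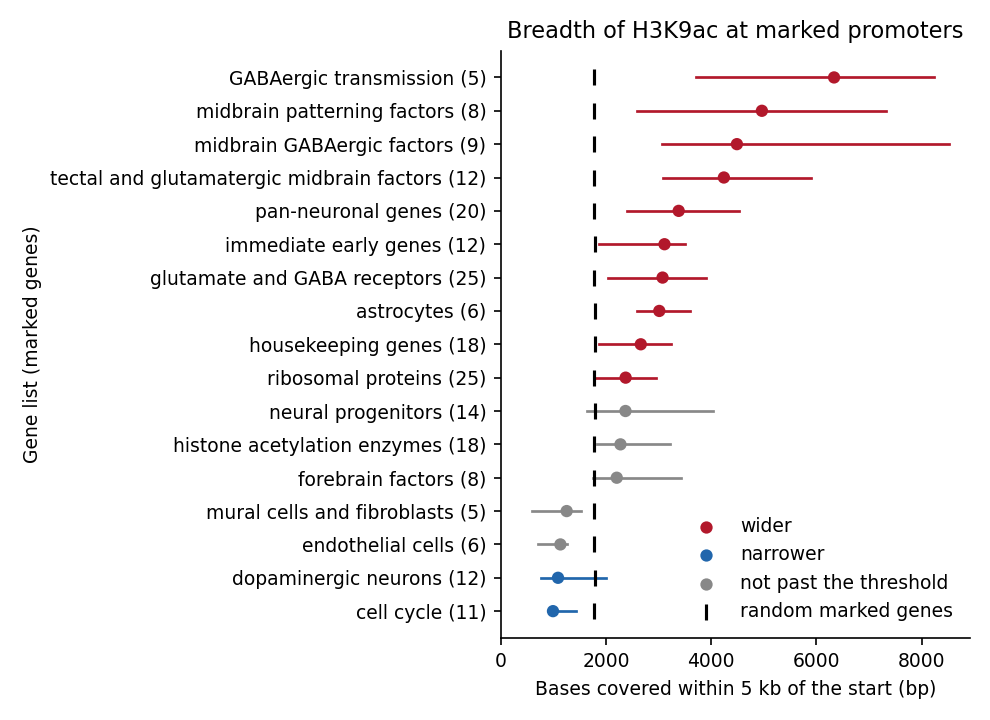
Bases covered by replicated H3K9ac peaks within 5 kb of the start (horizontal axis) over the marked genes of each list (number in brackets), with points for medians, lines for the quartiles and black ticks for the median of random marked genes. Lists of GABAergic transmission (6334), midbrain patterning (4962), GABAergic factors (4487) and tectal factors (4240) were the widest, and dopaminergic (1087) and cell cycle genes (991) the narrowest.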

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

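Of the tests in this part, the 1 on microglial, erythroid and liver genes without muscle genes, and the comparison of unmarked forebrain factors with CpG-matched unmarked genes, were chosen after the result was seen. Outside the main chromosomes the replicated list held 8 peaks, which no comparison used. They are given because a count of 0 would allow up to 3, which shows only that these scaffolds were not empty. Of these, 5 lay on an unlocalised scaffold of chromosome X, with folds of 4.00 to 7.80, 2 on one of chromosome 4 (3.60 and 8.40) and 1 on an unplaced scaffold (1.97). No group of samples was large enough for a search for outlying samples, and there was 1 group, so effects could not be compared between groups.

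About 50% of the peaks of each replicate were found in that replicate alone. With equally long lists the lower of the shares rose by 2.18 percentage points, to 51.1%. That rise fell between the bounds set beforehand (10 or more for the explanation, under 2 against it), and unequal length was ruled out as the main cause afterwards, because about 50% of peaks stayed unshared. Weak peaks close to the calling threshold were another candidate explanation. Its bound set beforehand was met, as 100% of the strongest 10% by q was shared in both replicates. That bound cannot decide the cause, because peaks with −log10 q of at least 27.2 and 22.9 could be shared under other causes too. The values show that unshared peaks were mostly weak, as only 17.0% and 21.6% of the weakest 10% were shared. Not all unshared peaks were weak. The strongest peaks in 1 replicate alone, with folds of 8.33 and 6.85, had −log10 q of 15.2 and 11.2. These values lie within the second strongest 10% of their lists (11.7 to 27.2 and 10.2 to 22.9). No biological explanation was tested, since the design has 1 group, and differences between the pools of animals stay open for the unshared peaks.

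Hox genes and several lists of other cell types and tissues were marked less often than other genes. Poverty in CpG does not account for the Hox genes, whose median promoter CpG ratio (0.722) was above that of all genes (0.614). Random genes matched on that ratio were marked in 87.2% of cases against 2.56% of Hox genes (permutation p = 0.0002, the smallest 10000 sets can give). The random genes were not clustered as Hox genes are, so this p overstates the evidence. For microglial, muscle, erythroid and liver genes together, with a median ratio of 0.262, matched genes were marked in 21.5% of cases against 4.35% (permutation p = 0.0008), so low CpG may account for much of the gap to other genes but not all of it. Without the muscle genes the shares were 5.88% and 17.5% with a permutation p of 0.0496, so close to the threshold of 0.05 that the evidence against low CpG is weak for these 3 lists.

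Of the 22 forebrain factors 8 were marked in midbrain tissue. A coding neighbour's start within 2 kb is not the cause, as 0 of the 8 had one. Starts of noncoding neighbours, and coding starts further away whose peaks are wide, were not checked and are not excluded. Forebrain cells in the dissected midbrain cannot be told apart from expression in the midbrain itself. Of the 14 unmarked forebrain factors 50% had a peak in the pooled list, which just met the bound set beforehand for such cells. Unmarked genes matched on CpG ratio had one in 32.8% of cases (permutation p = 0.268), and this later comparison of 14 genes keeps the question open. Foxg1, Tbr1 and Fezf2 had none there, whereas Dlx1, Dlx2 and Neurod6 had one. Lhx2 and Bcl11b were covered over 7793 and 5269 bases. No sort or gate would have removed such cells from this tissue.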

How the results depend on the processing

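Tests with 1 shift per chromosome, without genes with a neighbouring start, without receptor families in the background and with CpG-matched genes were chosen after the results were seen. Sharing between replicates stayed above random placement in all 4 alternatives, at 33.5 to 51.97% for replicate 1 and 35.7 to 69.9% for replicate 2, and has no version with a replicate left out. The Spearman correlation rose to 0.90 when peaks had to share 50% of both widths. That requirement keeps peaks of similar extent, and the cause was not tested further. Promoter enrichment, the number of marked genes (10768 to 14507) and both differences between promoter and distal peaks kept their direction and side of the threshold in all alternatives. The promoter share ran from 26.4% in the pooled list to 85.2% in the stricter list. With each replicate left out in turn, the results ran from 43.2 to 52.4% for the promoter share, 13353 to 13714 for marked genes, and, with all peaks of each own list rather than those with q of 0.01 or less, 2.93 to 3.47 for the fold difference and 461 to 486 bp for the width difference. The difference of midbrain patterning from forebrain factors was 10.3 to 25.8 percentage points and from Hox genes 44.1 to 59.0, against 33.3 in the stricter list and 71.3 in the pooled list. Lists marked more often numbered 8 to 9 and less often 8 to 9, lists wider 8 to 10 and narrower 2 to 4, with replicates left out.

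With CpG-matched genes 2 lists in place of 8 were marked more often, because matched genes are themselves marked more often. The tectal list (92.3%) then lay below its matched genes with an adjusted p of 1, and the cell cycle list (73.3%) fell below them (adjusted permutation p = 0.0258), whereas in the pooled list 100% of it was marked, more often than other genes (adjusted p = 0.00916, Fisher's exact test). In the pooled list 7 lists in place of 2 were narrower. Forebrain factors were marked in 68.2% (adjusted p = 1, Fisher's exact test), with a median of 770 covered bases (adjusted permutation p = 0.00105), and patterning factors had 1706 bases (0.498). The cause was not tested. In the stricter list 0 genes of oligodendrocyte precursors were marked (adjusted p = 0.0137, Fisher's exact test). The 4 marked in the full replicated list had folds of 3.20 to 5.40, none above that list's median of 5.40. The cause was not tested further. Of the other values for single lists, 297 kept their side of the threshold, 24 lost the call and 18 gained one. The 297 include changes of direction where neither value passed the threshold. The dopaminergic list (66.7%), for example, lay above other genes (62.1%) but below CpG-matched genes (78.7%). The unknown depth limits all counts of unmarked genes. No paired analysis was possible because there is 1 group.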

Other observations

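In this part the tests on gene families, noncoding genes, the X chromosome and the steps of the fold values were chosen after the lists had been seen. Gene families chosen by symbol added 29 further groups, of which 11 were marked more often than other coding genes, 8 less often and 10 neither. Against CpG-matched genes, only the Zfp zinc finger, potassium channel, Nduf and dopamine, serotonin and adrenergic receptor genes were still marked more often. Of those marked less often, clustered protocadherins and keratins stayed so. The call was lost for cytochromes P450 (adjusted permutation p = 0.622), beta-defensins (0.244), interleukins, chemokines, and taste and trace amine receptors. Clustered histone genes, forkhead and LIM homeobox factors gained it (adjusted permutation p = 0.000967 each). All 22 ephrin and Eph receptor genes, which guide axons in the tectum, were marked (adjusted p = 7.07e-05, Fisher's exact test), as were all 46 genes named Nduf, mostly subunits and assembly factors of a respiratory complex (1.33e-09), and all 78 mitochondrial ribosomal protein genes (5.64e-16). Against CpG-matched genes the call was lost for the ephrin and Eph receptor genes (92.9% of matched genes marked, adjusted permutation p = 0.622) and the mitochondrial ribosomal protein genes (94.4%, 0.0632), and kept for the Nduf genes (92.1%, 0.013). Of 28 dopamine, serotonin and adrenergic receptor genes 24 were marked (adjusted p = 0.0173, Fisher's exact test), above CpG-matched genes too (65.5%, adjusted permutation p = 0.00663). Of 21 cholinergic receptor genes 8 were marked, which did not pass the test (adjusted p = 0.055, Fisher's exact test), with 44.7% of CpG-matched genes marked. Of 94 potassium channel genes 71 were marked (0.0144, Fisher's exact test), also above CpG-matched genes (67.2%, adjusted permutation p = 0.0251). Of 57 clustered protocadherin genes, from which single neurons choose a few, 6 were marked (adjusted p = 3.29e-15, Fisher's exact test), against 66.5% of CpG-matched genes. These 6 were Pcdhac1, Pcdhac2, Pcdhga11, Pcdhgc3, Pcdhgc4 and Pcdhgc5, so 5 belong to the C-type members that many neurons express. Genes of a cluster are not independent, so p for this family overstates the evidence. Of 12 protocadherin genes outside the clusters 11 were marked (0.0544, Fisher's exact test).

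Of 12 LIM homeobox genes 4 were marked, which did not pass the test against other genes (adjusted p = 0.0909, Fisher's exact test) but was below the 93.6% of CpG-matched genes (adjusted permutation p = 0.000967). The 4 were Lhx9, Lhx5, Lhx1 and Lhx2, with a median of 8961 covered bases. Most of the unmarked ones had a weak peak in 1 replicate alone, such as Lhx4 in replicate 1 (fold 4.16). Noncoding genes over 5 kb from any coding start were marked in 7.88% of 5226 long intergenic RNA genes (exact interval 7.17 to 8.65%). Processed pseudogenes were marked in 0.670% of 9109. The widest intergenic RNA genes included the microRNA hosts Mir124-2hg (9851 bases) and Mir124a-1hg (9702), precursors of a microRNA of neurons, and the longest replicated peak of all (11134 bp, chromosome 7, 79498960 to 79510093) lay at Mir9-3hg, host of another neural microRNA. The strongest replicated peak (fold 40.4, chromosome 7, 73555954 to 73558555) lay 78 bp from the start of the noncoding gene 1810026B05Rik and 16149 bp from that of Chd2.

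A hypothesis set before its test was that wide promoters sit in neighbourhoods dense with distal peaks. The 680 widest of 13567 marked genes, with at least 4150 covered bases, had a mean of 1.73 distal replicated peaks within 100 kb, against 0.786 for the others, a ratio of 2.20 (permutation p = 0.0002, the smallest 10000 sets can give). The test came out as the hypothesis needs, but the relation may be part of a general density of peaks, since promoter peaks within the same distance also rose, from 4.79 to 6.09, and 42.4% of the widest genes had no distal peak there. Across all marked genes the Spearman correlation was 0.12.

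A smaller share of genes was marked on the X chromosome. Of its 948 coding genes 433 were marked (45.7%), against 63.4% of autosomal genes (p = 4.23e-27, Fisher's exact test). Leaving out olfactory and vomeronasal receptors took X from 948 to 941 genes and the autosomes from 20722 to 19310. These mostly unmarked genes lie almost all on autosomes, so leaving them out could only widen the difference, which became -22.0 percentage points. That outcome was therefore no test, but X holds too few of these receptors for them to explain its lower share. Marked genes on X had a median fold of 7.40, against 11.6 on autosomes. Other families on X were not tested, nor was any effect of the sexes, which both pools mixed. The number of X copies was not corrected for here, so the lower share and fold do not show less of the mark per copy.

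The deposited fold values lie on even steps of 0.35 in replicate 1, 0.33 in replicate 2 and 0.20 in the pooled list, with 50.99%, 63.2% and 67.2% of peaks within 0.001 of a whole multiple. A candidate explanation, written after the steps were seen, is that fold is fragments at the summit plus 1, over a background plus 1 that scales with library size and with the shortest width of the list (175, 190 and 185 bp). It predicts the pooled step from the replicates' steps with a difference of 0.000517%, and a value over 5% would have spoken against it. If so, the replicates may have had nearly the same depth, with a ratio of 0.989 for replicate 1 over replicate 2. The steps come from a search over step sizes that replaced a first estimate from gaps between neighbouring values, after that estimate had placed few peaks on its steps and had failed the prediction, so this result is weaker than its small difference looks.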
